A study of Homo sapiens with 6 samples.

How the data were processed

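The deposited table holds counts per gene for 6 libraries, and its unit was read as counts as the authors give it. Per the submitters' processing notes, reads were aligned to hg19 with STAR 2.5, counted with HTSeq 0.6.1 and tested with DESeq2. All columns of per-sample values were mapped to a sample by their names, with 0 left over. Of 48162 gene IDs, 45038 were matched to the reference names.

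The comparison, the filter, the test, the gene lists, the rule for naming genes and most alternatives were set before the data were examined. Alternatives with the intestinal-transcript batch, with both libraries of a date left out, with AGO2 and mitochondrial genes left out, with robust empirical Bayes, and with fry or an estimated correlation together with the block were chosen after the data were seen.

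Groups and dates were taken from the labels. Counts were fitted in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16, with TMM normalization, filterByExpr (min.count 10, min.total.count 15) and no block. The date of collection was added as a block in an alternative. The Benjamini-Hochberg adjusted p threshold was 0.05 over all tested genes. limma 3.58.1 (limma-voom, camera, fry) and DESeq2 1.42.0 were used for alternatives. Tables and figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The ± values are standard deviations, standard errors are the log2 fold change over the square root of F, and log2 ratios per date used a prior count of 2. The p-values measure spread between these samples, which may be technical, since the labels do not state whether dates were separate cultures.

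The 1 library per group and date were paired because the labels give a shared date. Deviations of the libraries of a date from the mean profile correlated at 0.0466, 0.154 and 0.513 in date order, so the pairing was weak for the first 2 dates. The common dispersion was 0.0292, a biological coefficient of variation of 17.1%. Depth ran from 20233819 to 34408699 counts per library, so counting error mattered only for scarce transcripts such as ALDH1L2, with 23 to 72 counts per library. Libraries correlated with each other at 0.9796 or more, and no 2 libraries of a group were duplicates.

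Gene lists were written from general knowledge and tested with camera at a preset correlation of 0.01, with adjustment over 18 lists. The same lists were tested with an estimated correlation and with fry. Some genes and 1 list are not reported here. Named genes were ALDH1L2, FN1 and AGO2, up to 10 genes each way past the threshold (none passed) and the members with the lowest p of each list: 4 for lists that passed and 2 for the others. Genes outside the rule (those called by DESeq2, those with the lowest p, those that differ between dates and the intestinal, plasma cell and haemoglobin genes) were chosen after values were seen. Lysosomal, endoplasmic reticulum, proteasome and respiratory chain lists were written after the leading genes were seen.

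Log2 differences between dates came from the fit with date and mimic as terms, with each date set against the mean of the others. Leading intestinal genes were those that led the largest component of variation within groups in a first look at the counts. They were summed as CPM without normalization. The trend with gene length was removed per library by a loess fit of its deviation from the mean log2 CPM on log length. Intervals for medians were bootstrapped over genes with 10000 draws.

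The code was tested on simulated data with the dispersions of these libraries. Genes were drawn independently, without differences by date or gene length, so these simulations test the code and not its performance in the real libraries. Of simulated changes, 20.9% of 1.5-fold, 76.1% of 2-fold and 97.0% of 4-fold were recovered, with 16 false calls. A list of 30 genes shifted by 0.3 was recovered at 0.28 with an adjusted p of 2.8e-12, and 0 of 20 unshifted lists were called. Members of these lists were independent, so this does not give the rate of false list calls in the real libraries. There, splits other than mimic against control called from 1 to 11 lists.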

Results

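ALDH1L2, the mitochondrial folate enzyme that oxidises 10-formyltetrahydrofolate and makes NADPH, had 1.79 times the level in Ago2 precipitates from HEK293 cells given the microRNA-219 mimic as in those given a negative control mimic. It did not pass the threshold over all genes, and neither did any other gene in the edgeR fit. FN1, which encodes fibronectin, had near equal means. Histone and mitochondrially encoded transcripts had a higher median with the mimic on each of the 3 dates of collection, and stress-response transcripts a lower one. Ribosomal protein and glutathione transcripts stood lower in most members, without the same direction on all dates. None of these list shifts passed once the correlation between genes was estimated (smallest adjusted p = 0.191), and the ribosomal median was above 0 on 5 September. Interferon-induced genes such as OAS2, RSAD2 and MX1 differed between dates, and were higher on 22 August with either mimic.

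HEK293 is an established human embryonic kidney line. Cells received Flag-tagged Ago2, the small-RNA-binding protein of the silencing complex, with either the mimic of microRNA-219 (3 libraries) or the negative control mimic (3 libraries). The tag was used to pull down Ago2, and the RNA that came with it was sequenced. Each group had 1 library from 22 August, 5 September and 18 September. A level here mixes how much of a transcript a cell held with how much of it was bound to Ago2, because input RNA was not used here.

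AGO2, the transfected gene, took 13.5, 16.7 and 12.6% of the counts of the mimic libraries and 11.7, 18.0 and 10.6% of those of the control libraries, in date order. Its mean was 142979 ± 22483 CPM with the mimic and 135262 ± 42530 CPM with the control (mean ± SD, n = 3 each; log2 fold change 0.08, SE 0.32, adjusted p = 0.999). AGO2 (ENSG00000123908) lies at chr8:141541264-141645718 of hg19. The 95% CI of this log2 fold change, −0.61 to 0.77, left room for unequal loads of the tagged protein's transcript. Mitochondrially encoded transcripts took 13.3, 6.25 and 7.27% of the counts with the mimic and 8.39, 5.66 and 6.48% with the control. Libraries held 31490366, 27777029 and 20379336 counts with the mimic and 25815380, 34408699 and 20233819 with the control. Of 48162 genes in the table, 28658 had a count in any library and 16233 were tested.

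Genes of the study's pathway came first. ALDH1L2 (ENSG00000136010, chr12:105413568-105478355) stood at 2.25 ± 0.298 CPM with the mimic and 1.26 ± 0.219 CPM with the control (n = 3 each), a log2 fold change of 0.84 (SE 0.27, 95% CI 0.26 to 1.42). Its ratio was above 1 on each date, with log2 values of 0.57, 1.05 and 0.79. The adjusted p was 0.999 over all genes. The exact permutation p was 0.1, the smallest that 3 against 3 can give. The transcript was scarce: 66, 72 and 42 counts in the mimic libraries and 38, 40 and 23 in the control libraries, in date order. The unadjusted p by edgeR was 0.00813, and a p as small was met by 56 of 16233 genes, where a uniform spread gives 132. Small p-values were scarcer than a uniform spread across all genes in this fit without a block, so this count does not show how unusual its place was.

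FN1 (ENSG00000115414, chr2:216225163-216300895), which encodes a matrix glycoprotein that accumulates in fibrosis, had 366 ± 155 CPM with the mimic and 350 ± 125 CPM with the control (log2 fold change 0.06, SE 0.30, 95% CI −0.59 to 0.72). The interval left out a 2-fold change of FN1 in either direction.

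**Figure D1:**
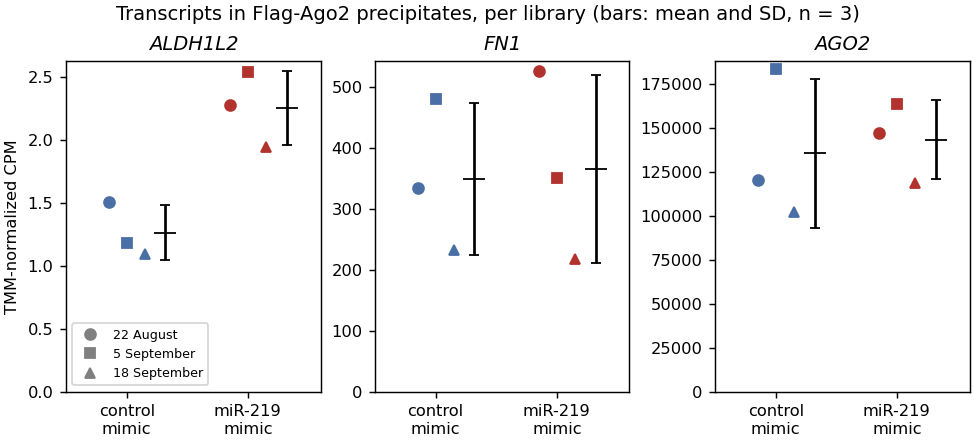
CPM of ALDH1L2, FN1 and AGO2 in each Ago2 precipitate, by mimic and date of collection. Bars give the mean and SD of 3 libraries.

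Across all genes, 0 were higher and 0 lower with the mimic at an adjusted p under 0.05 by edgeR without a block. There 488 had an unadjusted p under 0.05 (283 higher, 205 lower) against 812 expected by chance. With the date as a block 933 had an unadjusted p under 0.05 by edgeR, and again 0 passed either way. limma-voom called 0 genes (479 at an unadjusted p under 0.05). DESeq2 called 2 higher and 3 lower (433 at an unadjusted p under 0.05), among them KIF4A and CANX higher, and NEU1 and PPP1R14B lower. The median standard error of a log2 fold change was 0.18, and 13697 genes (84.4%) had a 95% CI inside a 2-fold change either way. A fold change of 2 or more was thus left out for most genes, though smaller ones were not. In simulated data of the same size 76.1% of 2-fold changes and 20.9% of 1.5-fold changes were recovered. Genes were drawn independently there, without differences by date or gene length, so recovery in the real libraries may be lower.

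KIF4A, CANX, NEU1 and PPP1R14B kept their direction on all 3 dates. They fall outside the rule fixed for naming genes and were chosen after the values were seen. Of the 488 genes with an unadjusted p under 0.05 by edgeR, 469 also kept their direction, so this agreement is no separate support. NEU1, the lysosomal sialidase, had 75.5 ± 4.03 CPM with the mimic and 122 ± 4.25 CPM with the control (n = 3 each; log2 fold change −0.69, SE 0.13), and its log2 ratio varied little between dates, at −0.68, −0.75 and −0.65 (DESeq2 adjusted p = 0.00373). PPP1R14B, an inhibitor of protein phosphatase 1, had 35.7 ± 5.74 against 63.4 ± 8.19 CPM (log2 fold change −0.83). KIF4A, a chromosome-bound kinesin of mitosis, had 56.2 ± 15.5 against 28.6 ± 5.42 CPM (log2 fold change 0.97). CANX, the calnexin chaperone of glycoprotein folding, had 755 ± 163 against 429 ± 46.8 CPM (log2 fold change 0.82). NEU1 (ENSG00000204386) lies at chr6:31825436-31830683.

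Further genes were among those with the lowest p by edgeR, none of them past the threshold. LAPTM4A, a lysosomal membrane protein, had a log2 fold change of −0.82, whereas LGMN, the lysosomal endopeptidase legumain, had 0.64 and HGSNAT, the lysosomal acetyltransferase of heparan sulfate, had 0.57. ETV4, an ETS-family transcription factor, had the largest negative value among the leading genes at −1.001. MAPK8IP2, a scaffold of the JNK kinases, had 0.69 and the p38 kinase MAPK11 had 0.88. In DESeq2 with the date as a block, 4 genes were called higher and 6 lower, with MAPK8IP2 and LGMN joining the higher genes and LAPTM4A, ETV4 and ACTBL2 the lower ones.

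Published targets of the mature 5' strand, miR-219a-5p, showed no shift that passed. The labels do not say which mature strand the mimic carries, so these may not be targets of the transfected RNA. The 20 tested genes had a median log2 fold change of −0.01, with 10 above 0 and 10 below (camera adjusted p = 0.723). HMGA2, the chromatin protein often studied as a target, had −0.27 and the fatty-acid elongase ELOVL7 had −0.27. Neither passed over all genes, and 0 members passed when adjusted over the list alone.

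Gene lists passed in 6 of 18 cases with the preset correlation, and 5 of them are described here. Replication-dependent histones had a median log2 fold change of 0.27 with 32 of 36 genes above 0 (camera adjusted p = 2.99e-07, with an estimated correlation 0.191). HIST1H2AC (0.75), HIST1H4H (0.66), HIST1H2BJ (0.63) and HIST1H2BD (0.51), parts of the nucleosome core, led the list. The list's median was 0.33, 0.21 and 0.30 on the 3 dates in order, and 14 of 36 genes kept the same sign on all dates. Without the mimic library of 22 August the median was 0.15 (adjusted p = 2e-05). Among members, 0 passed over all genes and 0 when adjusted over the list alone.

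Mitochondrially encoded genes had a median log2 fold change of 0.42 with 13 of 13 above 0 (camera adjusted p = 4.99e-06, with an estimated correlation 0.713). MT-ATP8 (0.67) and MT-ND4L (0.61), subunits of ATP synthase and complex I, led. The median was largest on 22 August, at 0.73 against 0.12 and 0.15 on the later dates. Without the mimic library of 22 August the median of the mitochondrial list was 0.01 (adjusted p = 0.967), while without both libraries of that date it was 0.18 (adjusted p = 0.000605). It was 0.65 without the mimic library of 5 September and 0.27 without the control library of that date. No member of the list passed over all genes (0) or when adjusted over the list alone (0).

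Cytosolic ribosomal proteins had a median of −0.19 with 75 of 81 genes below 0 (camera adjusted p = 1.42e-08, with an estimated correlation 0.744). RPL26L1 (−0.36) and RPL30 (−0.24) were among the lower, and RPS23 (0.44) was above 0 on every date. The list was lower on 22 August (−0.43) and 18 September (−0.22) and higher on 5 September (0.20). Without both libraries of 22 August its median was −0.05 (adjusted p = 0.988). It was −0.12, −0.34 and −0.0972 without the control library of 22 August, 5 September and 18 September. Counts of ribosomal members past the threshold were 0 over all genes and 0 when adjusted over the list alone.

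Glutathione genes, the metabolism named in the study's theme, had a median of −0.16 with 27 of 31 below 0 (camera adjusted p = 0.000123, with an estimated correlation 0.713). CHAC1, which degrades glutathione, had −0.31, GSTP1 −0.26, SLC3A2 −0.22 and GPX8 −0.21. The glutathione median was −0.30, 0.00 and −0.16 on the 3 dates, −0.0785 without the control library of 18 September (adjusted p = 0.0142), and −0.0815 without both libraries of 22 August (adjusted p = 0.196). The ATF4 and unfolded protein response targets had a median of −0.13 with 31 of 35 below 0 (camera adjusted p = 0.000142, with an estimated correlation 0.359). GARS, the glycyl-tRNA synthetase, had −0.33, and NUPR1, a stress-induced chromatin protein, had −0.47. The ATF4 median was −0.21, −0.11 and −0.10 on the 3 dates in order, and −0.0881 without the control library of 22 August (camera adjusted p = 0.0121). ALDH1L2 is itself an ATF4 target, and its value, which did not pass, had the other sign: the 34 other members had a median of −0.14 (bootstrap 95% CI over genes −0.16 to −0.08). That interval takes genes as independent and does not measure spread between libraries. In both lists 0 members passed over all genes and 0 when adjusted over the list alone.

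**Figure D2:**
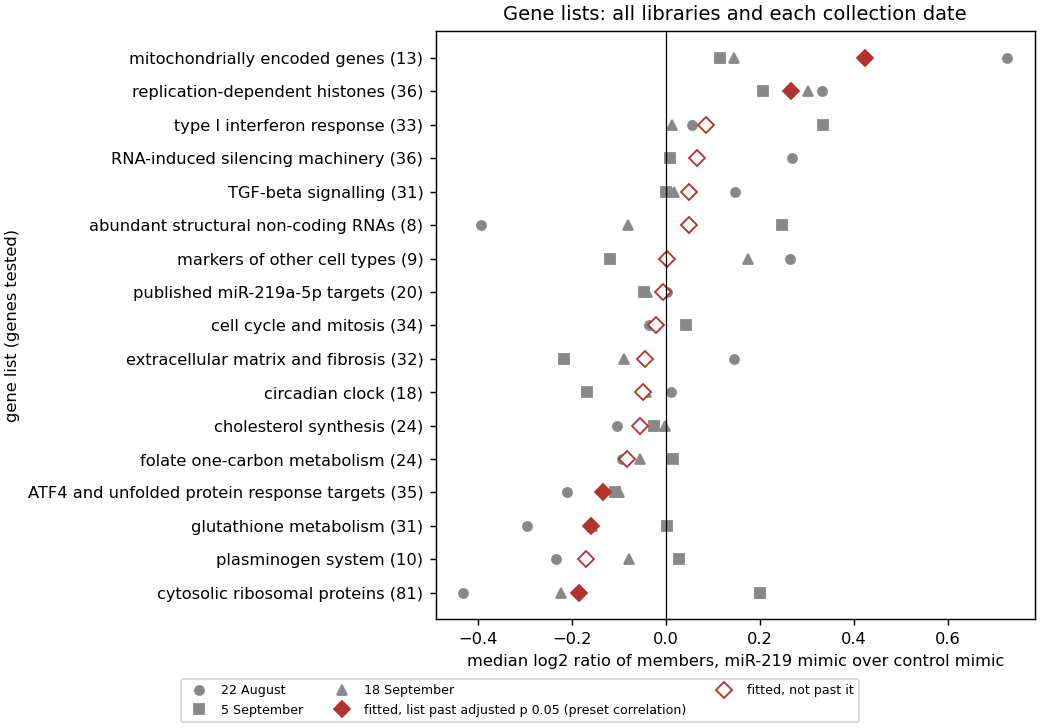
Median log2 ratio of mimic to control per gene list on each date of collection. Lists without an equal direction on the 3 dates included the ribosomal proteins.

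None of the 6 list calls was left when the correlation between genes was estimated from the data, where the smallest adjusted p was 0.191, or with the rotation test fry, where it was 0.16. These calls thus depended on how far members of a list were taken to vary together between libraries.

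Other lists did not pass in the fit without a block. Folate one-carbon genes had a median of −0.08 (adjusted p = 0.557; SHMT1, the cytosolic serine hydroxymethyltransferase, −0.25). Extracellular matrix and fibrosis genes had −0.04 (adjusted p = 0.249; the laminin chain LAMB1 −0.36, the protease inhibitor TIMP1 −0.29). The plasminogen system had −0.17 (adjusted p = 0.168; the urokinase receptor PLAUR −0.41). TGF-beta signalling had 0.05 (adjusted p = 0.0812), with LTBP1, which stores latent TGF-beta in matrix, at 0.66 and the differentiation inhibitor ID1 at 0.68. The silencing machinery had 0.07 (adjusted p = 0.183; the decapping helicase DDX6 0.40, the Dicer partner TARBP2 −0.24). Cholesterol synthesis had −0.05 (adjusted p = 0.193; NSDHL −0.36, EBP −0.19), and cell cycle and mitosis had −0.02 (adjusted p = 0.557; CCNB1 −0.29, KIF11 0.22). The circadian clock had −0.05 (adjusted p = 0.69; RORA 0.28, TEF −0.20). Structural non-coding RNAs had 0.05 (adjusted p = 0.68; SNHG1 −0.29, GAS5 −0.22), and markers of other cell types had 0.00 (adjusted p = 0.808; MBP 0.22, CD14 −0.25). In each of these lists 0 members passed over all genes and 0 when adjusted over the list alone. The plasminogen list passed in 6 of 25 alternative settings, the matrix list in 5, and the TGF-beta and silencing lists in 4 each. The remaining lists of this paragraph passed in none.

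The interferon list did not pass between mimics, with a median of 0.08 (adjusted p = 0.557, with an estimated correlation 0.879; OAS3 0.83, ISG20 −0.25). With the date as a block the call changed: the median was 0.15 and the adjusted p 0.000257 (with an estimated correlation 0.534). Counts of members past the threshold were 0 over all genes and 0 when adjusted over the list alone. Without the block the call also came and went with libraries left out: the median was −1.12 without the mimic library of 22 August (adjusted p = 2.81e-09) and 1.69 without the control library of that date (adjusted p = 4.8e-21). It was 0.37 and 0.35 without the mimic libraries of 5 and 18 September (adjusted p = 0.00307 and 0.000579), −0.17 without the control library of 5 September (adjusted p = 0.0335) and −0.16 without that of 18 September (adjusted p = 0.0916).

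Interferon-induced genes set 22 August apart. On that date 27 of 33 list members were higher than on the other dates by an adjusted p under 0.05, with a median log2 difference of 2.59 (with an estimated correlation, camera adjusted p = 0.046). RSAD2, the antiviral enzyme viperin, was higher by 4.44, the oligoadenylate synthetase OAS2 by 4.15, the mitochondrial nucleotide kinase CMPK2 by 3.87, IFIT1 by 3.38 and the antiviral GTPase MX1 by 3.20. Sensors of foreign RNA took part as well, with DDX58 (RIG-I) at 2.59 and IFIH1 (MDA5) at 2.20, and so did the transcription factor IRF7 (1.84). Summed interferon transcripts were 2353 CPM with the mimic and 2119 CPM with the control on 22 August, 678 and 574 CPM on 5 September, and 582 and 590 CPM on 18 September. The response was therefore carried by both transfections of that date. In all, 50 genes differed between dates, and 54 were higher and 1 lower on 22 August than on the other dates.

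CTGF, which encodes a matricellular protein, was lower on 18 September by a log2 value of −2.10 (SE 0.13, adjusted p = 0.0085). Its levels in date order were 136, 120 and 33.4 CPM with the mimic and 232, 188 and 43.5 CPM with the control. The ankyrin repeat protein ANKRD1 (−1.79) and the keratin KRT17 (−1.61) fell with it. On 18 September 8 genes were lower and 0 higher than on the other dates. The other 5 were interferon-induced (IFIT2 −2.25, IFIT3 −1.96, OAS3 −1.83, SAMD9 −1.57 and DDX58 −1.42) and were set against a mean that included 22 August, while on 5 September 0 differed.

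Libraries also differed in transcripts that HEK293 cells are not known to make. The 21 leading intestinal and plasma cell genes, among them IGHA1, PIGR and FABP1, summed to 0.730, 19.9 and 38.9 CPM with the mimic and to 65.5, 1.63 and 56.1 CPM with the control, in date order. IGHA1, the heavy chain of immunoglobulin A, had 0, 146 and 135 counts with the mimic and 422, 0 and 257 with the control. Haemoglobin beta (HBB) had 23319 counts, or 678 CPM, in the control library of 5 September and at most 2 counts in the other 5. These genes followed neither mimic nor date.

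**Figure D3:**
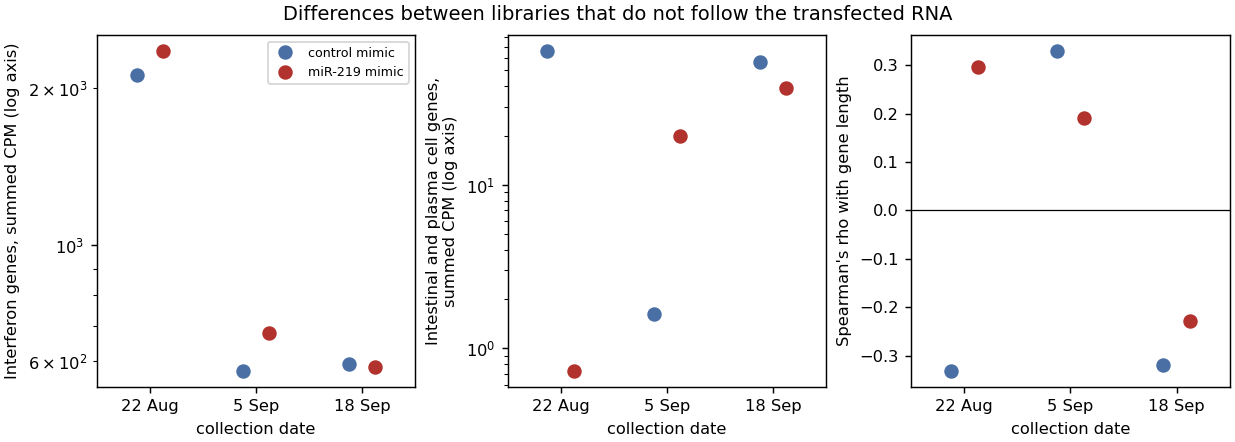
Summed interferon and intestinal transcripts, and rank correlation of each library's deviation with gene length, by date and mimic. Each point is 1 library.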

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

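With 3 libraries per group, an unstated number of separate cultures and no input RNA, small changes could not be seen, and shifts in binding could not be told from shifts in amount. For the changes of setting below the cause was not tested, apart from the calls with date and batch and the list calls with an estimated correlation. Genes higher and lower with the mimic went from 0 and 0 to 6 and 14 with no filter on low counts, 2 and 3 with DESeq2, 4 and 6 with DESeq2 and the date as a block, and 1034 and 1290 with date and intestinal-transcript batch (a choice made after the data were seen). They stayed at 0 and 0 with the replicate block alone in edgeR (933 at an unadjusted p under 0.05, smallest adjusted p 0.61), with limma-voom, with other normalization and with any library left out. ALDH1L2 stayed between 0.69 and 0.98 over 24 settings and passed in 1, with date and batch (0.84). The 6 list calls became 7 with the block, 10 with date and batch, 0 with an estimated correlation, 0 with fry, and 0 and 0 with each of these and the block. They ranged from 5 to 10 with libraries left out.

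Directions reversed mostly near 0. With batch as a term, OAS3 was −0.12 and the interferon list −0.30. With only the 4 libraries that carry intestinal transcripts, MT-ATP8 was −0.0349, MT-ND4L −0.012, OAS3 −1.46, and the lists of interferon −1.52, mitochondrial genes −0.14, structural non-coding RNAs −0.16, clock 0.10 and published targets 0.0168. Published targets were 0.0139 with upper-quartile normalization and 0.00918 without the filter, markers of other cell types −0.0408 without the filter and non-coding RNAs −0.0217 with a stricter filter. With libraries left out the ranges were: AGO2 −0.0867 to 0.36, FN1 −0.33 to 0.38, MT-ND5 −0.0117 to 0.86, OAS3 −1.09 to 2.28, interferon −1.12 to 1.69, silencing machinery −0.00623 to 0.172, TGF-beta −0.00383 to 0.139, non-coding RNAs −0.23 to 0.27, cell cycle −0.0469 to 0.0384, clock −0.126 to 0.0613, matrix −0.204 to 0.0426, other cell types −0.13 to 0.12 and published targets −0.0747 to 0.025. Seed matches in 3' untranslated regions and counts of 7-base seeds were not run, because they need transcript sequences that were not used here.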

Other observations

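Genes of the lysosome and of the secretory route were looked at as groups because NEU1 and LAPTM4A were among the leading genes lower with the mimic. These 4 lists were chosen after that result was seen. Leading genes already seen were left out of them, both lower ones such as NEU1 and LAPTM4A and higher ones such as LGMN and HGSNAT. The p-values were adjusted over these 4 lists alone, and the trend with gene length was not removed for them. Lysosomal hydrolases and membrane proteins had a median log2 fold change of −0.12 with 29 of 36 below 0 (camera adjusted p = 3.37e-05, with an estimated correlation 0.301). Endoplasmic reticulum genes of translocation, glycosylation and folding had −0.11 with 28 of 36 below 0 (camera adjusted p = 0.000171, with an estimated correlation 0.301), although CANX, a chaperone of that compartment, had 0.82. Proteasome subunits had −0.16 with 26 of 29 below 0 (camera adjusted p = 5.19e-06, with an estimated correlation 0.301). Nuclear respiratory chain genes had −0.16 with 25 of 30 below 0 (camera adjusted p = 3.29e-05, with an estimated correlation 0.324). Neither of these lists belongs to the lysosome or the secretory route, so shifts of this size were not particular to those compartments.

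NEU1 cleaves sialic acid from glycolipids and glycoproteins in lysosomes, and it stood lower in the Ago2 precipitate. NEU1 kept a log2 fold change between −0.73 and −0.65 over 24 alternative settings. A lower level in the precipitate may follow decay of a targeted transcript, or less binding to Ago2; input RNA was not used here, so the 2 could not be told apart. KIF4A, from 0.75 to 1.15 over the same settings, stood higher, and there too greater binding could not be told from a larger amount of transcript. Seed matches of these genes were not tested.

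The tests of 3 patterns below were chosen in part after the results were seen: those of list counts over splits, of simulated data and of gene length in the blocked fit, and of unseen intestinal genes were written before their values, the others after. Splits of 6 libraries into 3 and 3 number 10, too few for a p. The real split had 0 genes past the threshold, 488 at an unadjusted p under 0.05 and 6 lists, and the highest of the other splits had 441, 3905 and 11. As many were reached in 10, 6 and 4 of the 10 splits. The split that calls 441 genes (mimic 22 August, mimic 5 September and control 5 September against the rest) points to a structure of the samples, and those 3 libraries are the deepest and the ones richer in long genes. Among the other splits that part all 3 dates, the counts at an unadjusted p under 0.05 were 61, 696 and 487, with 2, 4 and 1 lists.

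IGHA1, PIGR, FABP1 and other intestinal transcripts may come from outside RNA or reads, from the mimic or from the date. These genes were picked because libraries of the same group differed in them. An overlap of mimic and control libraries was thus close to fixed in advance, and it cannot test a response to the mimic. The highest control library had 89.7 times the summed CPM of the lowest mimic library. The control library of 5 September (1.63 CPM) was below the mimic libraries of 5 and 18 September (19.9 and 38.9 CPM). The date alone is an unlikely cause for these genes, since libraries of a date were apart by ratios of 89.7, 12.2 and 1.44, in date order. Intestinal genes not used to see the pattern were higher in the 4 libraries by a median log2 value of 0.599, between the 2 limits set. Of these 25 genes, 6 had 1 CPM or more in all libraries, so part of the list could hardly show small outside amounts. Plasma cell genes not used to see the pattern were higher by 0.736, and liver genes by 0.247. Profiles of the leading genes correlated at 0.893 to 0.952 between the 4 libraries, though these genes were picked from the pattern. An outside source present in different amounts thus could not be told from other causes. The 678 CPM of HBB in the control library of 5 September belongs to a library with few intestinal transcripts, and a second source is possible.

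The shifts of histones, ribosomal proteins, ATF4 targets and glutathione genes may reflect transcript length, shared variation of their members or the mimic. Libraries differed by length: the rank correlation of a library's deviation with gene length was 0.30, 0.19 and −0.23 for the mimic and −0.33, 0.33 and −0.32 for the control, in date order. Removing this trend kept 6 of the 6 list calls. The histone median went from 0.27 to 0.29, away from 0, which argues against length as the cause of the histone shift. Ribosomal proteins went from −0.19 to −0.13, glutathione genes from −0.16 to −0.0958 and ATF4 targets from −0.13 to −0.0952. Length is thus not the whole cause for these lists, though it may be a part. An estimated correlation left 0 calls, which is in line with members of a list varying together between libraries. The histone list had the smallest adjusted p with that correlation, 0.191, and its response to the mimic stays open, since reads shared between near-identical histone genes were not examined.

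LAPTM4A, KIF4A and CANX were among the leading genes of a fit with date and intestinal-transcript batch both as terms, chosen after the data were seen, which called 1034 genes higher and 1290 lower with 1 residual degree of freedom, while DESeq2 with the same terms called 228 in all. At most 4 genes were called in 20 simulated data sets without an effect, but genes were drawn independently there. In the real libraries the same fit with labels exchanged and another batch called as many as 433. The simulation thus could not settle whether few degrees of freedom gave the calls. Gene length is not the whole cause, as 1772 were called after its trend was removed, 1417 of them among those called before. Ratios from separate libraries correlated at 0.222 after that removal. Before it the value was 0.235, and 0.521 among the 10269 genes above 8 CPM. But this sets 18 September against the mean of 2 dates whose own ratios correlated at −0.238 before the removal, and at −0.309 above 8 CPM. Above 8 CPM each of them correlated with 18 September, at 0.330 and 0.304. Only 9 distinct assignments of labels and batch exist (the real one ranked 1, the highest other called 433), so an effect of the mimic could not be told from chance. With that fit, ALDH1L2 had a log2 fold change of 0.84 and an adjusted p of 0.00863.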
